A study of Mus musculus with 4 samples.

How the data were processed

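The study profiled circular RNAs (circRNAs) in C2C12 cells, an established mouse myoblast line that fuses into myotubes when serum is lowered. The cells had been kept in differentiation medium with 2% horse serum for 3 to 4 days. There were 4 libraries: 2 of total RNA and 2 of RNA prepared by RPAD. RPAD removes linear RNA by RNase R digestion (30 min), polyadenylation of the linear RNA that is left, and depletion of poly(A)+ RNA. The labels' protocol speaks of HeLa RNA in the RNase R reaction, while the cell line of all 4 libraries is labelled C2C12; the labelled line is used here, and this was not resolved. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 2 libraries of a group came from separate cultures. The p-values of the abundance tests therefore measure the spread between these libraries, which may be technical. Tests across circles take circles as units, and their p-values do not measure that spread.

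Per the labels' protocols, ribosomal RNA was depleted from both kinds of RNA, cDNA was amplified with the NuGEN Ovation system, sonicated, ligated to adaptors, size-selected, amplified by 17 cycles of PCR and sequenced on an Illumina HiSeq2500. Per the submitters' processing notes, cutadapt, TopHat and Cufflinks 2.2.1 were used, with the mm9 genome. The program that called the back-splice junctions is not given in the sources used here. PCR copies were not marked by molecular identifiers, so intervals and floors cover counting error only.

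Each deposited file lists the circRNAs of 1 library, and its values are raw counts of back-splice junction reads per circle, per the file headers. A read count is whole and at least 1, and it equals the number in the circle's name in 100% of entries. The deposited files also give a score from 0 to 3 per junction, per the file headers, whose meaning is not given in the sources used here; it served only to leave out junctions above 0 in 1 alternative. The files divide circles into exonic circles, joined at annotated exon ends, and intronic circles, which begin at a 5' splice site and end inside the intron. The libraries held 38850 and 35981 back-splice reads for total RNA and 150478 and 191246 for RPAD. These are totals of back-splice reads and not sequencing depth, so every change in abundance is relative to other circRNAs of a library, either all or those tested.

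A circle was defined by chromosome, start, end and strand, and a circle absent from a file was given 0 reads. Positions are mm9, counted from 1. The files name 8067 transcripts, of which 4585 have Ensembl-style names and 3482 are assembled models. The files do not pair these with gene symbols, and 0 of them matched the name tables at hand. Circles and hosts are therefore given by position. The circRNA in the series title and the gene lists fixed before the data were examined were not analysed here. Transcript identifiers that shared a junction or an intron were linked into 6536 host groups, and reads were summed over each group.

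Abundance was tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test, TMM scaling of back-splice reads, a low-count filter (filterByExpr with a minimum count of 5 and a minimum total of 10) and group as the only term. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The SE of a log2 fold change was its absolute value divided by the square root of F, so it restates the test. DESeq2 1.42.0 was run on the same counts as an alternative. The filter's minimum count scales with each library's total, so fewer reads sufficed in total RNA than in RPAD. It kept 924 circles and 1425 host groups. Every scaling, totals alone included, used only reads of the features kept. For circles these numbered 11190 and 10867 in total RNA and 48848 and 64601 in RPAD. Log2 fold changes are therefore relative to the other tested features. Listed circles and shares were compared by exact two-sided permutation tests, which with 2 libraries against 2 cannot give a p below 0.333. Shares within a library carry exact Clopper-Pearson 95% intervals. Thinned counts are means of 20 random draws. Length was related to log2 fold change by Spearman correlation across circles, with 100000 permutations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

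The rule for named items, the tests of the group comparisons and most alternatives were fixed before the data were examined. The rule named the 8 circles with the highest mean abundance and, since no item passed the threshold, the 3 with the smallest p in each direction, for circles and for host groups. Other circles named below were chosen after their values were seen. A fold against a group with 0 reads in both libraries is a bound that covers the counting error of the 0 reads alone. Reads of the other group were taken as counted, so the bound can be too high, most of all where they are few. The bound was computed with a floor of 3 reads over the group and the groups' totals of 74831 and 341724 reads. These totals hold all back-splice reads, so bounds and log2 fold changes are on different scales.

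The fits were tested on simulated data with 200 changed features, counted before the low-count filter. Every feature of both groups was given the same spread, although the real spread differed between groups. With either RPAD library left out, the coefficient of variation estimated for circles was 0.82. At the common spread of the full circle fit (biological coefficient of variation 1.60), 0 of 200 circles were recovered at 4-fold, 64-fold and 1024-fold changes. At a coefficient of 0.3, 19 of 200 were recovered at 4-fold and 199 of 200 at 64-fold, with 6 false calls. For host groups at the real coefficient of 1.56, 0 of 200 were recovered at each of those 3 sizes, and at 0.3 all 200 were recovered at 64-fold, with 4 false calls. The alternatives covered scaling, test, filter, replicate block, each library left out, feature set, read minimum, depth, length measure and host definition.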

Results

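Back-splice junctions, at which the end of an RNA segment is joined to its own start, were read in differentiated C2C12 cells from 2 libraries of total RNA and 2 of RPAD RNA. The comparison asks which circular RNAs come into view, and in what proportion, once linear RNA is removed. Total RNA libraries 1 and 2 listed 18809 and 16477 circles, and RPAD libraries 1 and 2 listed 15460 and 26403. The 4 libraries together held 69136 circles, of which 4074 were exonic and 65062 intronic. Of all circles, 90.6% were listed in 1 library, and 240 were listed in all 4 (72 exonic and 168 intronic).

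Fewer exonic circles were listed in RPAD RNA, and the mean number of reads per listed exonic circle was higher. Total RNA listed 1944 ± 174 exonic circles (SD, n = 2) and RPAD 638 ± 197 (SD, n = 2), with no overlap between groups. Reads per exonic circle were 8.14 ± 0.442 in total RNA and 115 ± 4.29 in RPAD (SD, n = 2 each). Reads on exonic circles numbered 16179 and 15392 in the total RNA libraries against 55971 and 91868 in the RPAD libraries. Each of these differences had an exact permutation p of 0.333, the smallest that 2 against 2 libraries can give. With every library thinned to 15392 exonic reads, total RNA kept 1925 ± 147 exonic circles and RPAD 499.5 ± 90.2 (SD, n = 2 each). Reads per exonic circle at that depth, which follow from these counts, were 8.02 and 31.3 on average.

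**Figure D1:**
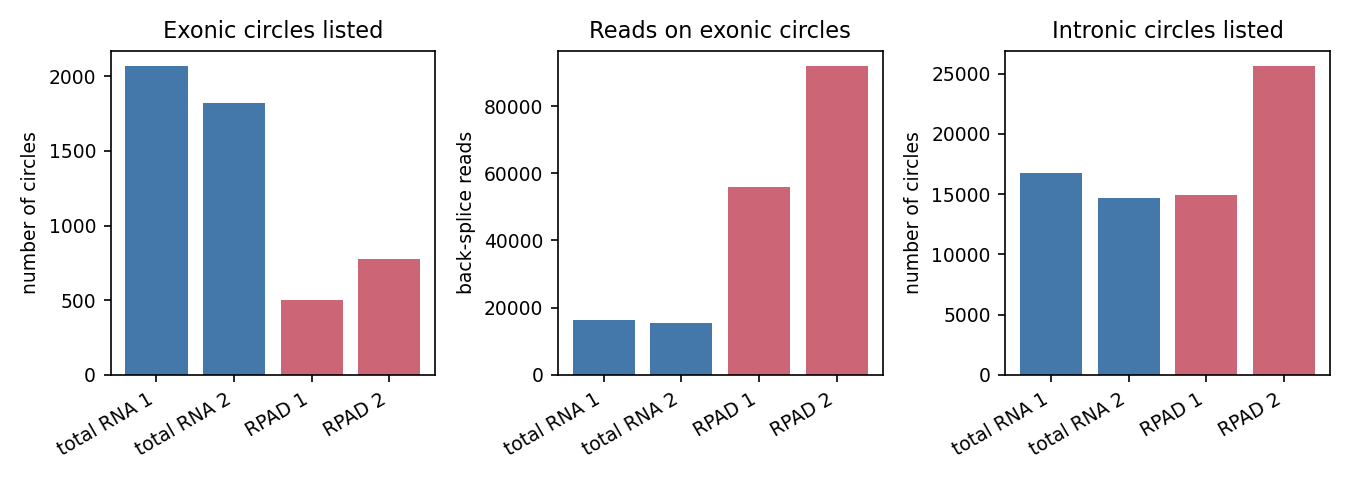
Bars give, for each of the 4 libraries, the number of exonic circles, the back-splice reads on exonic circles and the number of intronic circles. Exonic circles numbered 2067 and 1821 in total RNA against 499 and 777 in RPAD, while their reads numbered 16179 and 15392 against 55971 and 91868.

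With exonic and intronic circles counted together, the direction of the difference depended on depth. Without thinning, total RNA listed 17643 ± 1649 circles and RPAD 20932 ± 7738 (SD, n = 2 each; exact permutation p = 1). With at least 5 reads required, 824 and 802 circles were listed in total RNA and 6879 and 6807 in RPAD (exact permutation p = 0.333). The direction of the difference without a read minimum depended on RPAD library 2: the difference of RPAD from the total RNA mean was 3288.5 circles with it and -2183 without it. After thinning to 35981 reads, total RNA listed 17125 ± 916 circles and RPAD 10799 ± 1304 (SD, n = 2 each; exact permutation p = 0.333). Circles with a single read made up 74.0% and 69.1% of those listed in total RNA, and 17.5% and 33.8% in RPAD.

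The share of reads on intronic circles lay in the RPAD libraries on either side of that in total RNA. Intronic circles held 58.4% (95% interval 57.9 to 58.8) and 57.2% (56.7 to 57.7) of back-splice reads in total RNA libraries 1 and 2. The RPAD libraries gave 62.8% (62.6 to 63.0) and 52.0% (51.7 to 52.2). The means were 57.8% ± 0.801 and 57.4% ± 7.67 (SD, n = 2 each; exact permutation p = 1). The difference of means was -5.83 points without RPAD 1 and 5.02 points without RPAD 2, so no difference between groups could be read from these libraries. As a share of distinct circles, intronic ones made up 89.0% ± 0.0441 of the total RNA lists and 96.9% ± 0.201 of the RPAD lists (SD, n = 2 each; exact permutation p = 0.333). Introns with at least 1 circle numbered 4050 and 3246 in total RNA and 1304 and 1672 in RPAD. Single-exon circles held 11.4% ± 0.785 of exonic reads in total RNA and 11.9% ± 0.190 in RPAD (SD, n = 2 each; exact permutation p = 0.667).

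The circle with the highest mean share of reads over the 4 libraries lay on chromosome 2, from 76691662 to 76694423 on the minus strand. It joins 5 exons, 124 to 128 of its transcript model, into 414 nt. It had 1212 and 1093 reads in total RNA and 3371 and 3383 in RPAD. The log2 fold change relative to other circles was -0.95 (SE 0.56), with an edgeR Benjamini-Hochberg adjusted p of 0.692. Without the low-count filter the log2 fold change was -0.14. Its host group, chromosome 2 from 76543468 to 76820604 (transcript ENSMUST00000111882), held more exonic circles than any other host group, 78 across the 4 libraries. Exonic circles of this host took 16.7% ± 0.678 of exonic reads in total RNA and 10.8% ± 3.77 in RPAD (SD, n = 2 each; exact permutation p = 0.333).

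Circles that begin at exon 124 carried most exonic reads of that host. Their share was 81.2% ± 0.947 in total RNA and 79.0% ± 2.09 in RPAD (SD, n = 2 each; exact permutation p = 0.333, the smallest possible). The circle of exons 124 to 128 took 43.8% ± 3.43 and 45.2% ± 0.442. The circle of exons 124 to 133 (10 exons, 948 nt) took 13.3% ± 4.31 and 12.9% ± 5.18, and that of exons 124 to 141 (18 exons, 1878 nt) took 14.4% ± 6.13 and 10.7% ± 0.503. The host listed 42 and 47 exonic circles in total RNA and 22 in each RPAD library.

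**Figure D2:**
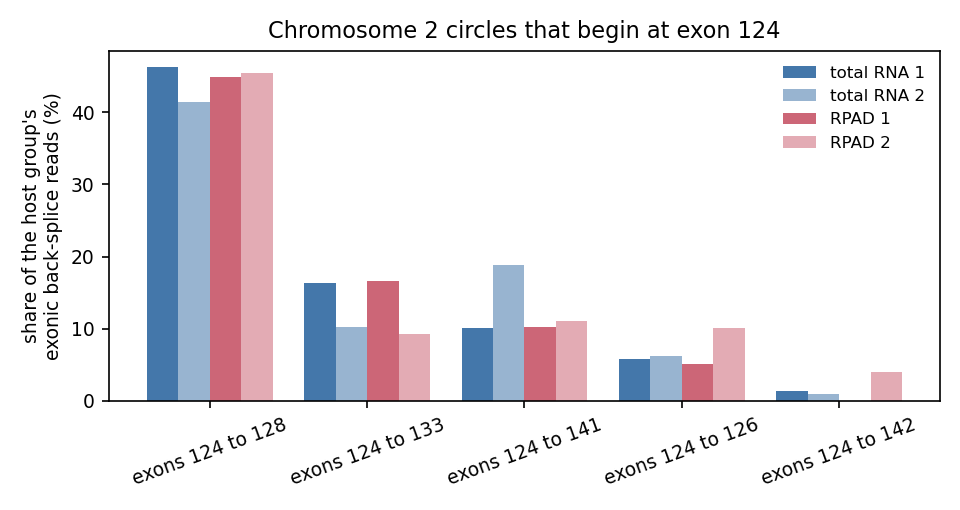
Bars give the share, in percent, of the chromosome 2 host group's exonic back-splice reads that each of 5 circles beginning at exon 124 took in each library. The circle of exons 124 to 128 took 46.2% and 41.4% in total RNA and 44.9% and 45.5% in RPAD.

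Among the other abundant circles, chromosome 5 from 3747021 to 3772787 (4 exons, 873 nt) had 252 and 117 reads in total RNA and 3393 and 3881 in RPAD, more than any other circle in each RPAD library. Its log2 fold change was 1.78 (SE 0.87), with an edgeR Benjamini-Hochberg adjusted p of 0.484. With 1 library left out the log2 fold change was 1.25 to 2.61, and without RPAD 1 it was 2.34 and passed the threshold (edgeR, Benjamini-Hochberg adjusted p = 0.0490; 0.0490 to 1.00 over its alternatives). A single-exon circle of 1970 nt on chromosome 4, from 83937597 to 83939566, had 268, 175, 935 and 2281 reads in total RNA 1, total RNA 2, RPAD 1 and RPAD 2. Its log2 fold change of 0.43 became -0.72 without RPAD 2. The circle on chromosome 19 from 41620365 to 41630191 (3 exons, 515 nt) had 158 and 276 reads in total RNA and 1031 and 722 in RPAD, and its log2 fold change of -0.48 became 0.26 without the low-count filter. The circle on chromosome 9 from 66387869 to 66414710 (6 exons, 538 nt) had 137, 269, 532 and 1156 reads. Its log2 fold change was -0.31 with TMM and 0.04 with DESeq2 size factors. The circle on chromosome 19 from 53887738 to 53892510 (4 exons, 1345 nt) had 82 and 21 reads in total RNA, 0 in RPAD 1 and 2888 in RPAD 2. The adjusted p of these last 4 circles was 0.999 with edgeR and Benjamini-Hochberg adjustment.

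No circle passed the threshold in the test of RPAD against total RNA. Of 924 circles (462 exonic and 462 intronic), edgeR called 0, with 162 at an unadjusted p under 0.05 (16 higher in RPAD and 146 lower). DESeq2 also called 0, with 164 at an unadjusted p under 0.05. The balance of directions depended on the filter: at an unadjusted p under 0.05, edgeR gave 30 higher and 42 lower with at least 10 reads in 2 libraries, and 11 higher and 2 lower over all 69136 circles. The smallest Benjamini-Hochberg adjusted p from edgeR was 0.179. Leaving out an RPAD library left the spread to be estimated from the total RNA pair, and edgeR then called 184 circles without RPAD 1 and 214 without RPAD 2. The median log2 fold change of the tested circles was -0.15 with TMM, 0.04 with totals alone and 0.18 with DESeq2 size factors. On the TMM scale the median was -1.07 for exonic and 0.14 for intronic circles. Among exonic circles, 128 of 462 had 0 reads in both RPAD libraries and 13 had 0 in both total RNA libraries. For intronic circles the numbers were 16 and 21. The filter asked for a minimum share of reads in at least 2 libraries, which took fewer reads in total RNA. These counts and medians therefore describe only circles that passed it. Of all exonic circles listed, 2919 were only in total RNA and 705 only in RPAD. The groups did not overlap for 48.7% of exonic and 27.5% of intronic circles. Chance gives 33.3% only where all 4 libraries vary alike and no filter is applied. Across tested circles, log2 abundance correlated at 0.463 between the total RNA libraries and at 0.0581 between the RPAD libraries. These shares are therefore not read as a difference between groups.

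The circles with the smallest p had 0 reads in every library of one group. Chromosome 6 from 47731623 to 47731724, a circle of 102 nt that spans a whole single-exon transcript (ENSMUST00000083011), had 0 reads in both total RNA libraries. It had 909 and 941 in RPAD, at least 135-fold higher. No annotated intron flanks it on either side, and how its junction arose was not tested. Chromosome 9 from 49314958 to 49315758 (1 exon, 801 nt) had 245 and 728 reads in RPAD, at least 71.0-fold higher. Chromosome 1 from 130090037 to 130118280 (5 exons, 832 nt) had 262 and 385, at least 47.2-fold higher. In the other direction, chromosome 4 from 16079064 to 16085577 (4 exons, 545 nt) had 147 and 121 reads in total RNA and 0 in both RPAD libraries, at least 408-fold lower. Chromosome 6 from 136821688 to 136824326 (3 exons, 245 nt) had 97 and 91 reads in total RNA, at least 286-fold lower in RPAD. An intronic circle on chromosome 19, from 10698129 to 10698480, had 6 and 8, at least 21.3-fold lower. The edgeR Benjamini-Hochberg adjusted p was 0.179 for 5 of these and 0.187 for the chromosome 1 circle. The folds are bounds for the counting error of the 0 reads alone. They can be too high, most of all for the intronic circle with 6 and 8 reads. Of exonic circles with at least 20 reads in RPAD 1, 68.9% had 0 reads in RPAD 2, and 73.6% in the other direction. A count of 0 in RPAD therefore need not mean low abundance.

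Reads summed over host groups gave no call in the main edgeR test, while other planned settings gave some. Of 1425 host groups, edgeR called 0, with 376 at an unadjusted p under 0.05 (17 higher and 359 lower), and the smallest Benjamini-Hochberg adjusted p was 0.135. DESeq2 called 103, of which 100 were lower in RPAD. Of those 100, 97 had 0 reads in both RPAD libraries. Without RPAD 1 edgeR called 537 host groups, and without RPAD 2 it called 624. The median log2 fold change was -0.94 with TMM, -0.87 with totals alone and -0.69 with DESeq2 size factors. Without the low-count filter, over 6536 host groups, the median was -3.64, and 36 were higher and 68 lower at an unadjusted p under 0.05.

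The host group with the smallest p was the chromosome 2 group described above, with 2843 and 2909 reads in total RNA and 8624 and 8369 in RPAD. Its log2 fold change of -0.89 (SE 0.13) lay close to the median of the 1425 tested host groups. Without the low-count filter it was -0.67, against a median of -3.64. A host on chromosome 7, from 149688663 to 149701913 (ENSMUST00000078497), had 237 and 179 reads in total RNA and 0 in both RPAD libraries, at least 633-fold lower. The chromosome 4 host from 16065048 to 16085577 had 149 and 121 against 0 and 0, at least 411-fold lower. Both folds are bounds for the counting error of the 0 reads alone. With more reads in RPAD, the chromosome 1 host from 130048321 to 130132203 (ENSMUST00000097596; 82 circles, 14 exonic) had 29 and 18 reads in total RNA and 1851 and 1881 in RPAD, a log2 fold change of 3.88 (SE 0.87). The chromosome 5 host from 3722546 to 3772787 had 305 and 139 against 3483 and 4050, a log2 fold change of 1.67 (SE 0.51). The edgeR Benjamini-Hochberg adjusted p of each was 0.135. With the replicate number as a block, edgeR called 2 host groups, the chromosome 2 group (adjusted p = 0.0272; 0.0114 to 1.00 over its alternatives) and the chromosome 7 group (adjusted p = 0.0483; 1.62e-07 to 1.00). DESeq2 called the chromosome 7 group and the chromosome 4 group, with Benjamini-Hochberg adjusted p of 0.00882 and 0.0135 (1.45e-05 to 1.00 over the alternatives of the latter). It also called the chromosome 6 host of the 102 nt circle (Benjamini-Hochberg adjusted p = 0.0266; 2.19e-06 to 1.00 over its alternatives), the third host with more reads in RPAD, whose adjusted p with edgeR was 0.135.

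Many circles of total RNA were not read in RPAD RNA. Of 229 circles with at least 5 reads in both total RNA libraries, 29.3% (95% interval 23.5 to 35.6) were listed in both RPAD libraries, 30.6% (24.7 to 37.0) in 1 and 40.2% (33.8 to 46.8) in neither. Among 67 exonic circles with at least 20 reads in both total RNA libraries, 35 were in both RPAD libraries, 20 in 1 and 12 in neither. Those in neither included chromosome 9 from 22448189 to 22483508 (7 exons, 786 nt; 67 and 66 reads in total RNA) and chromosome 4 from 108151478 to 108152346 (1 exon, 869 nt; 49 and 81 reads).

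**Figure D3:**
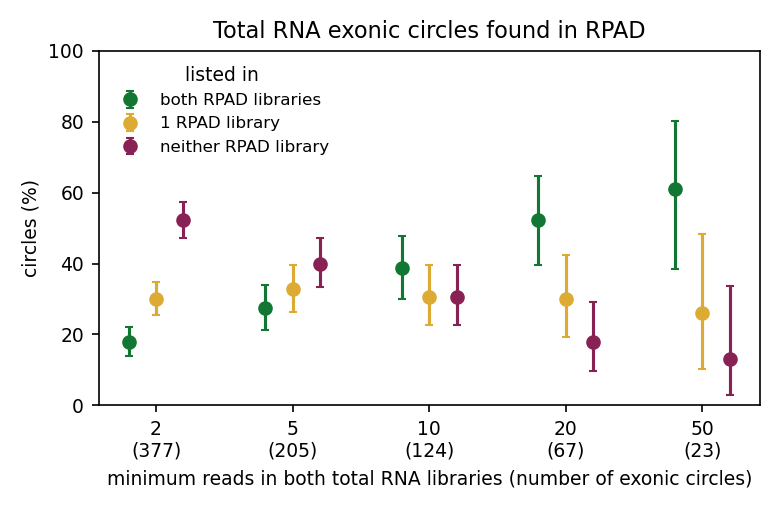
Points give the share, in percent, of exonic circles listed in both, 1 or neither RPAD library, against the minimum number of reads in both total RNA libraries, with exact 95% intervals and the number of circles in brackets. The share in both RPAD libraries was 27.3% at a minimum of 5 reads and 60.9% at a minimum of 50.

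The RPAD libraries shared few exonic circles with each other. Of 1155 exonic circles listed in either RPAD library, 121 were in both (10.5%), against 519 of 3369 (15.4%) for total RNA. Of exonic circles with at least 20 reads in RPAD 1, 68.9% (95% interval 63.0 to 74.3; 188 of 273) had 0 reads in RPAD 2. In the other direction the share was 73.6% (68.6 to 78.1; 256 of 348). In total RNA the shares were 27.3% (20.4 to 35.2) and 28.7% (21.6 to 36.6). Chromosome 4 from 133275452 to 133278966 (3 exons, 780 nt) had 54 and 141 reads in total RNA, 0 in RPAD 1 and 2083 in RPAD 2. Chromosome 2 from 34287523 to 34299926 (3 exons, 567 nt) had 135, 192, 181 and 0 reads.

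**Figure D4:**
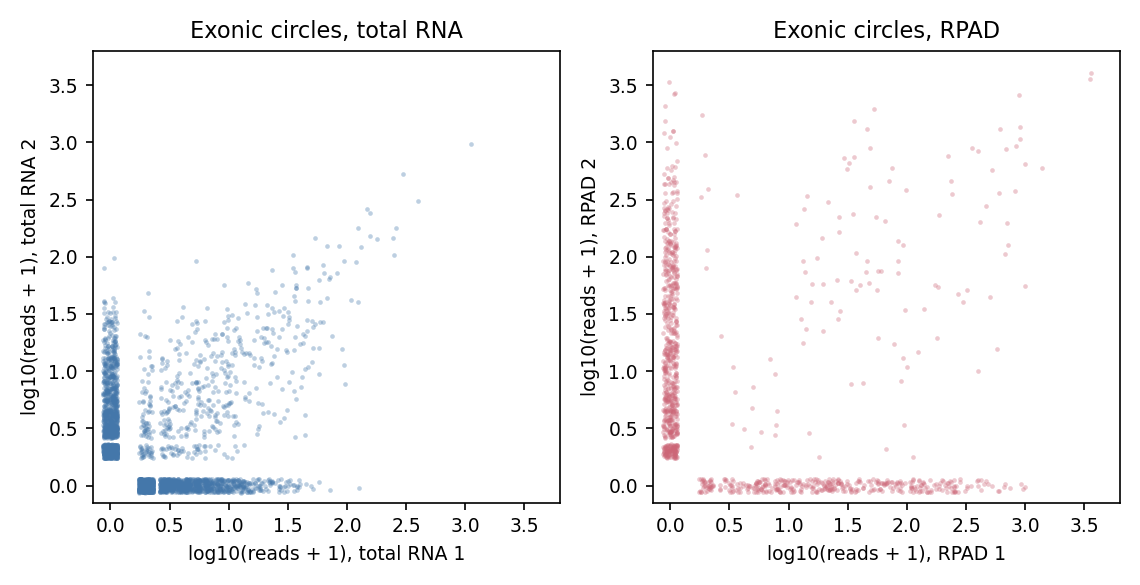
Each point is an exonic circle, placed by log10(reads + 1) in replicate 1 and replicate 2 of total RNA (left) and of RPAD (right), with a small random shift to part equal values. Circles with 0 reads in one replicate lie along an axis, and in RPAD 121 of 1155 circles lie off both axes.

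Longer circles had lower log2 fold changes across all tested circles, while within exonic circles no trend was detectable. The Spearman correlation of spliced length with log2 fold change was -0.21 over 924 circles (permutation p = 1e-05, the smallest the permutations can give). Within the 462 exonic circles it was -0.04 (permutation p = 0.39), within the 462 intronic circles -0.11 (permutation p = 0.02), and within the 407 exonic circles of more than 1 exon -0.08 (permutation p = 0.107). The first quartile of length, 84 to 140 nt, held 9 exonic circles of 232 and had a median log2 fold change of 0.16. The last quartile, 778 to 5866 nt, held 229 exonic circles of 231 and had a median of -1.20. Within intronic circles the medians of the 4 length quartiles, from short to long, were 0.29, -0.01, 0.51 and -0.15, with no steady fall. Within exonic circles they were -0.37, -1.55, -0.86 and -1.27, highest in the shortest quartile and with no steady fall after it. Circles are not independent replicates, and the same intron can give many circles with different ends.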

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

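Circles summed per intron, junctions with score 0, transcript identifiers as given, the feature sets other than all circles for lists and recovery, recovery without an RPAD library, and bounded fold changes were chosen after seeing the data. Calls of circles stayed at 0 with edgeR or DESeq2 under every setting that kept both RPAD libraries; leaving out 1 library gave 0 to 214 calls. In those fits the lone library is assumed to vary like the other group. Calls of host groups were 103 with DESeq2 and 2 without the low-count filter, and 0 to 624 with 1 library left out. The 0 calls rest on a common spread at which simulated changes of 1024-fold were not recovered. The simulation gave all features that same spread, so it does not give the power for features that vary less.

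The replicate block gave 0 calls of circles and 2 of host groups. Deviations of same-numbered libraries correlated at 0.0463 for circles and 0.0123 for host groups. With 2 pairs and RPAD libraries that correlated at 0.0581 with each other, this does not settle whether a number marks a shared culture.

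The difference in listed circles was 3288.5 (RPAD minus total RNA). It was 10128 with at least 2 reads and 6030 with at least 5, but -6325 after thinning, -1306 for exonic circles, -1425 for exonic circles thinned, -2160 for introns and -1996 for host groups, and -2183 to 8760 with 1 library left out. The intronic share differed by -0.405 points of reads and 7.94 points of distinct circles, and by -5.83 to 5.02 points with 1 library left out. The share in neither RPAD library was 49.0% at a minimum of 2 reads and 31.2% at 10, and 52.0% to 59.0% missing from the RPAD library kept. The length correlation was -0.0402 within exonic circles and -0.0802 within the 407 exonic circles of more than 1 exon, since intronic circles count as single-exon; with 1 library left out it was -0.30 to -0.16. The cause of these differences was not tested.

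Of 237 alternative values for named items, 198 kept their direction and side of the threshold, 30 passed the threshold in the same direction and 9 changed sign, 1 of which also passed it. The chromosome 4 circle starting at 83937597 had a log2 fold change of -0.72 to 1.32 with 1 library left out, and the chromosome 19 circle starting at 41620365 had 0.26 without the filter. The chromosome 9 circle starting at 66387869 had 0.0373 with DESeq2 size factors and with DESeq2, 0.49 without the filter, and -1.37 to 0.50 with 1 library left out. The chromosome 19 circle starting at 53887738 had -2.38 with the replicate block and -10.29 to 3.95 with 1 library left out; -10.29, without RPAD 2, was past the threshold. The planned gene list and title circRNA alternatives were not run.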

Other observations

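Some introns gave circles in all 4 libraries. An intron on chromosome 2, from 52057532 to 52058028, held 159 and 132 back-splice reads in total RNA and 1766 and 1252 in RPAD, spread over 57, 42, 64 and 66 circle ends. An intron on chromosome 1, from 71675111 to 71675889, held 219, 153, 677 and 365 reads. Of 7857 introns with a circle, 132 had one in all 4 libraries. For this count each circle was given 1 intron across libraries. The total RNA libraries then had 4062 and 3260 introns and the RPAD libraries 1311 and 1680, slightly more than in the counts above. Mitochondrial circles classed as intronic were listed in total RNA 1, where an interval from 74 to 241 had 502 reads over 55 ends, and in no other library. Whether this interval is an intron was not tested. Circles that span a whole transcript had 15 and 14 reads in total RNA and 963 and 1018 in RPAD, and 909 and 941 of the RPAD reads came from the chromosome 6 circle of 102 nt.

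Of the tests of explanations, that of the culture difference and that of long circles were set before their results were seen; the other 5, the interval around the length difference and the values given without a test were chosen after.

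Exonic circles with many reads in one RPAD library and 0 in the other were common: 444 of 549 distinct circles with at least 20 reads in at least 1 of them (80.9%, 95% interval 77.3 to 84.1). Taken from each library in turn, so that circles with 20 reads in both count once for each, the share was 71.5%, where Poisson counting at the depth of the other library predicts 7.92e-06%, which argues against too few reads. Few molecules amplified many times was to show as both RPAD libraries keeping at least 80% of exonic circles when thinned to 15392 reads. RPAD 1 kept 87.7% but RPAD 2 kept 72.2%, so the prediction was not met. RPAD 2 was thinned hardest, to 16.8% of its exonic reads, against 27.5% for RPAD 1 and 22.1% for the total RNA libraries. The total RNA libraries kept 51.7% and 53.8%, less than RPAD 2. The 80% bar was also set after the data were seen, so missing it does not count against this explanation. A difference between cultures would make circles of 1 RPAD library lean to the total RNA library of the same number, and the odds ratio was 1.13 (95% interval 0.695 to 1.83; Fisher's exact p = 0.641), below the 2 set for it, a test that takes the numbers to mark cultures. Looked at after these results, and not counted as tests, the share missing from the other RPAD library was 68.9% and 73.6% at 20 reads. It was 68.6% and 66.1% at 100 reads. Of 67 circles with at least 20 reads in both total RNA libraries, 20 were in 1 RPAD library. The cause stays open, and loss of molecules before amplification was not excluded.

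Of 205 exonic circles with at least 5 reads in both total RNA libraries, 82 were missing from both RPAD libraries. Permuting 1 RPAD library within 5 bins of abundance gave a median of 71 (central 95%, 65 to 77; permutation p = 0.0009), fewer than observed. The share missing was smaller among abundant circles: of 67 with at least 20 reads in both total RNA libraries, 12 were missing from both RPAD libraries. Each of the 5 bins can still span a range of abundance, which alone would raise joint loss above the permutations. The test therefore cannot decide whether loss from each RPAD library was independent. Missing circles were not longer: their median spliced length was 743.5 nt against 927.5 nt for circles found in both, a difference of -184 nt (bootstrap 95% interval -376 to 130; permutation p = 0.141), so loss of long circles cannot be told apart from no length effect with these numbers. Sensitivity of particular circles to RPAD, for example through nicking, is a hypothesis that was not tested.

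Intronic circles begin at the annotated 5' splice site as their class is defined, but few ended where a lariat branch point may lie. The share of intronic reads ending 10 to 50 nt upstream of the annotated 3' splice site was 2.21% and 1.03% in total RNA and 0.270% and 0.189% in RPAD, which argues against lariats closed near that site as annotated. Lengths set by the library or the reads were to show as few circles under 100 nt and a weak correlation with intron length. At least 100 nt were spanned by 99.8% of circles in each total RNA library and 99.7% in each RPAD library. Intron length correlated with median circle length across introns at 0.150, 0.147, 0.0779 and 0.0890 (Spearman). The prediction was met, but its limits were set after the data were seen. A weak correlation would also arise wherever circle length does not follow intron length, so these values do not single out this explanation. Branch points of unannotated splice sites stay open, and no biological explanation other than lariats was tested.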
